A study of Mus musculus with 6 samples.

How the data were processed

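RNA was sequenced from nephron progenitor cells, the cells of the fetal kidney that form the nephron epithelium, sorted from mouse embryos at embryonic day 18.5. Per the labels' protocols, CD-1 females were mated with males carrying a Cre transgene driven by Six2, and pregnant females were assigned at random to a control diet or to food restriction for the whole pregnancy. The sample labels give the restricted diet as 30% of daily caloric intake and the series text gives 70%; the sources used here do not settle which was fed. Kidneys were digested with collagenase and dispase, GFP-positive cells were sorted, and RNA was taken up in TRIzol, per the labels' protocols. Per the labels' protocols, a SMARTer Pico kit for stranded total RNA libraries was used, which keeps both coding and non-coding RNA. There were 3 libraries per diet, 6 in all. The design text calls them biological replicates, but nothing in the labels ties a library to a litter or to a number of embryos, so p-values measure the spread between these libraries.

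Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.6.0 and DESeq2 1.22.1 with genome build GRCm38; the strand setting of the counting is not given in the sources used here. The deposited table holds 52386 genes with whole-number read counts per library, not normalized, made by the authors. For 6727 genes, mostly short RNAs, immunoglobulin segments and genes on patch scaffolds, it marks no count, which leaves 45659 counted genes. The authors' second set of values is the signal obtained by dividing each count by a size factor of its library, 1 constant per library. Such normalized counts are deposited for 25157 genes, those with a summed count of at least 10; the highest summed count without a normalized value was 9. The authors' size factors, recovered as count over normalized count, were 1.08, 0.934 and 0.933 for control replicates 1 to 3 and 0.568, 1.27 and 1.53 for food-restricted replicates 1 to 3. The same deposited table gives the authors' own DESeq2 comparison as log2 fold changes with standard errors, test statistics (a score per gene), p-values and adjusted p-values.

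The test planned before the data were examined was a count model for whole counts, with limma-trend on log2(value + 1) as the written fallback for normalized values. The missing-value mark in the count columns kept them from being declared as counts, so the fallback was the test used. A count model such as edgeR was not run, and DESeq2 was not run anew. The authors' normalized counts were tested with limma 3.58.1 in R 4.3.3: log2 of the normalized count plus a pseudocount of 1, a linear model with diet as its only term, and empirical Bayes with a mean-variance trend. All 25157 genes with normalized values were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are food-restricted over control. Values per diet are means of normalized counts with the SD over 3 libraries. The results of the authors' comparison and of several limma settings had been looked at before this fit was made the principal one. The fallback was written in advance, but for a table without whole counts. This table held whole counts, so using the fallback departed from the plan.

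A set of 44 gene lists, covering kidney cell types, metabolism, growth signalling, cell cycle, stress responses and RNA classes, was fixed before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 44 lists. A second run estimated the correlation for each list, and fry asked whether a list's genes move on balance one way. Members were counted from the gene test over all genes and again adjusted over the list alone. Some genes stand on more than 1 list. The named genes were chosen by a rule written in advance: the 12 highest and 12 lowest fold changes among called genes with a mean log2 CPM of at least 2, no overlap between diets and an established symbol; a fixed set of 9 genes; and up to 4 members of smallest p per list. Called members of a list with 5 or fewer calls in a direction, and Slc22a8, Gm6166, Kap, the X-linked genes and the Sema genes, were named only after their values were seen. Some genes that these rules name are not reported here.

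Total counts ranged from 6515127 to 16763479 per library. The test was also run on simulated data drawn at the libraries' depths with a variance 2.5 times that of counting error. Among 200 changed genes it recovered 38.8% of those changed 1.25-fold, 79.1% of those changed 1.5-fold and 87.9% of those changed 2-fold, with 5 false calls among 142. The shifted list was found and 1 of 40 unshifted lists was called. Changed genes and list members were drawn from the better expressed genes only, so recovery among weakly expressed genes was not simulated. The simulated variance was 2.5 times counting error at every level, while the mean chi-square per gene between libraries of a diet ran from 2.97 to 10.3. For genes that vary more than simulated, the rates of recovery and of false calls may be optimistic. Simulated genes varied independently and the lists were random. The simulation therefore does not give camera's rate of false calls on lists of correlated genes. Within each diet the libraries differed from each other by a median chi-square of 2.35 to 2.83 times that of counting error alone, so none was merged or left out. Exon lengths and GC content came from the GENCODE M21 annotation and matched 99.8% of tested genes. All per-library columns of the table were mapped to a labelled sample.

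The alternatives were upper-quartile scaling, scaling by the trimmed mean of M values, limma-voom, wider and narrower filters, other pseudocounts, other thresholds, abundant RNA classes removed before scaling, the replicate number as a block, and each library left out in turn. Removing each library's trends against exon length and GC (lowess over genes with a mean of at least 50, span 0.3), and the trimmed-mean scaling, were added after the data were seen. Genes with near-identical copies (replication-dependent histones, Cwc22, Tpm3-rs7, ribosomal protein genes) and the overlapping transcripts of the ribosomal RNA repeat are uncertain where the authors' counting split or dropped shared reads.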

Results

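Gene expression was measured in 6 libraries of sorted GFP-positive nephron progenitor cells from E18.5 mouse kidneys, 3 from control pregnancies and 3 from food-restricted pregnancies. Total counts were 12338593, 10881013 and 10686582 for control replicates 1 to 3. They were 6515127, 14188081 and 16763479 for food-restricted replicates 1 to 3. Protein-coding genes took 83.9% to 86.4% of the counts and mitochondrial genes at most 1.58%. A single transcript of the ribosomal RNA repeat, Gm42418, took 6.59%, 7.87% and 7.37% of the counts in the controls and 7.42%, 5.27% and 4.54% in the food-restricted libraries. On the first principal component (43.8% of the variance) the controls lay between -10.7 and -7.75 and the food-restricted libraries between 5.84 and 11.6. Food-restricted replicate 1, the shallowest library, stood apart on the second component (18.3% of the variance) at -12.1.

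The sorted cells carried the genes that define nephron progenitors in every library. Six2, the transcription factor that keeps these cells undifferentiated and whose promoter drove the transgene, stood at 364 ± 16.7 CPM in controls and 349 ± 12.5 CPM in food-restricted libraries (SD, n = 3 each). Eya1, its cofactor, stood at 819 ± 13.6 and 787 ± 22.1 CPM. Not all markers of other cells were low. Lrp2, a proximal tubule gene, stood at 354 ± 12.8 CPM in controls, near the level of Six2, and at 198 ± 1.61 CPM in food-restricted libraries, and Cubn, its partner, at 41.0 and 24.2 CPM. The stromal collagen Col1a1 stood at 82.7 and 101 CPM. Others were low: endothelial Pecam1 was at 5.13 CPM in controls and 6.02 CPM in food-restricted libraries, ureteric Ret at 0.497 and 0.614 CPM and haemoglobin Hba-a1 at 6.62 CPM in both. The median level of the 25 self-renewal genes lay between 71.5 and 88.1 CPM over the 6 libraries, against 1.07 to 1.72 CPM for endothelial genes, 0.656 to 1.31 CPM for ureteric genes, 0.890 to 1.31 CPM for loop and distal tubule genes and 0.750 to 1.66 CPM for erythroid genes. Stromal genes had medians of 6.28 to 14.8 CPM, podocyte genes 9.94 to 16.4 CPM, proximal tubule genes 8.51 to 14.8 CPM and macrophage genes 0.609 to 1.81 CPM. Nephron commitment genes had medians of 26.4 to 36.7 CPM.

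The comparison of the diets asked how gene expression in the sorted cells differed with maternal food restriction through pregnancy. The lists of proximal tubule, G2/M phase, replication-dependent histone, unfolded protein response and sterol synthesis genes were lower in the food-restricted libraries, while Six2 and its partners did not pass the test. Single genes of nephron commitment (3 of 21), renal stroma (4 of 17), macrophages (3 of 14) and insulin-like growth factor signalling (7 of 28) rose. Those 4 lists passed as higher at the preset correlation, but not with an estimated correlation (adjusted p = 0.0624, 0.0624, 0.0624 and 0.126 with an estimated correlation). Of 25157 genes tested with limma, 1193 were called: 563 rose and 630 fell. Diet was the only term of the model. A difference between the diets in the sex, genotype or litter of the embryos therefore cannot be told apart from diet in these calls. The same holds for a difference in the mix of cell types within the sort, for every list. Most changes were small. The median absolute log2 fold change of the called genes was 0.35, and 125 of them (60 higher, 65 lower) had an absolute log2 fold change of at least 1. The libraries of the diets did not overlap for 1136 of the called genes and for 4950 of all tested genes (19.7%, where chance gives 10%). The count fell to 748, 766 and 765 without control replicates 1, 2 and 3, to 736 without food-restricted replicate 2 and to 564 without food-restricted replicate 3. Of the 44 gene lists, 24 passed camera, 16 lower and 8 higher; 6 of these held with an estimated correlation and 18 did not.

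**Figure D1:**
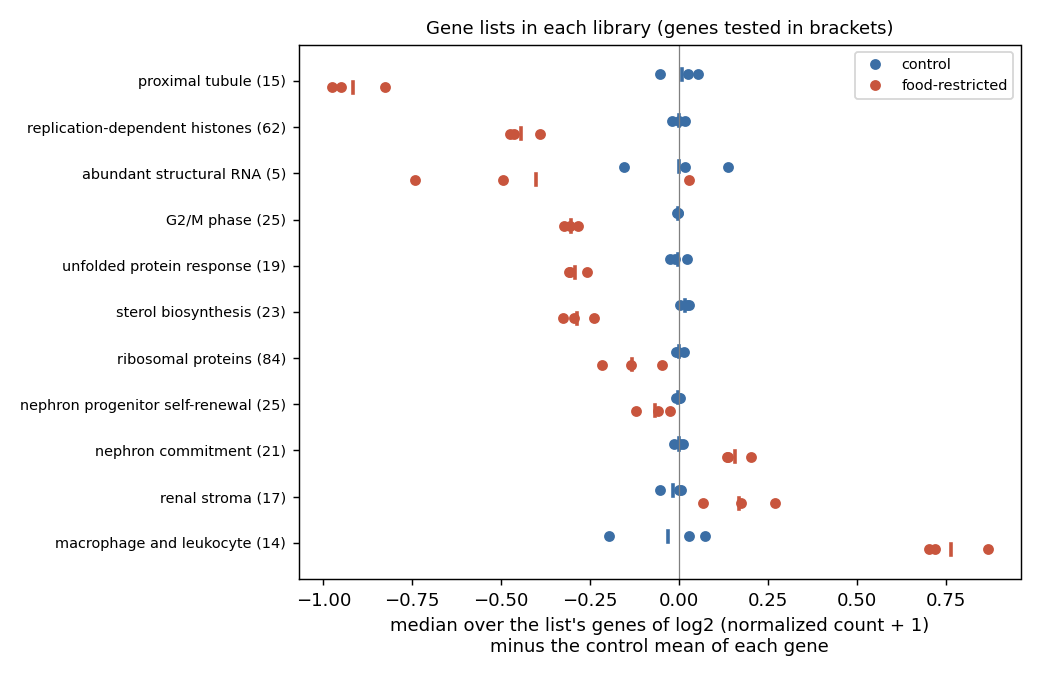
Median over each gene list of log2 (normalized count + 1) minus the gene's control mean (horizontal axis, log2 units), 1 point per library, with a line at the mean of the 3 libraries of a diet. The proximal tubule points of the food-restricted libraries lie between -0.98 and -0.83, and for abundant structural RNA the point of food-restricted replicate 1 (0.029) lies among the controls.

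Proximal tubule genes, which serve reabsorption in the mature nephron, showed the largest fall of the cell type lists. Of 15 tested genes, 14 fell and none rose, the same counts as when adjusted over the list alone. The median log2 fold change was -0.84, a control level 1.79-fold that of the food-restricted cells. Lrp2 (megalin, the main endocytic receptor of the proximal tubule; ENSMUSG00000027070, GRCm38 chromosome 2, 69424340 to 69586065) fell from 4045 ± 146 to 2259 ± 18.4 normalized counts (SD, n = 3 each; log2 fold change -0.84, SE 0.046, limma adjusted p = 6.36e-23). Ass1, an enzyme of arginine synthesis, fell from 336 ± 33.7 to 137 ± 19.3 (-1.29, limma adjusted p = 4.56e-12). The organic anion transporter Slc22a6 fell from 231 ± 10.9 to 101 ± 6.76 (-1.18, limma adjusted p = 3.32e-09). Only Slc22a8 did not pass, at 36.0 ± 7.71 and 32.6 ± 8.53 (-0.15, limma adjusted p = 0.878). All 3 food-restricted library medians lay below all 3 controls, and the list passed camera (adjusted p = 7.73e-37; adjusted p = 0.00606 with an estimated correlation).

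No other list of mature kidney, endothelial or erythroid markers passed the test. Among 13 podocyte genes, Foxc2 rose (0.35, limma adjusted p = 0.00579) and Podxl fell (-0.99, limma adjusted p = 0.0209); 2 rose and 2 fell adjusted over the list alone, and the list had a median of 0.06 and a mean of -0.12 (test direction higher, camera adjusted p = 0.742). None of 14 loop and distal tubule genes was called (median -0.01, mean 0.11, test direction higher, camera adjusted p = 0.503). Hoxb7 was the 1 ureteric gene of 13 that fell (-0.59, limma adjusted p = 0.00151; list median -0.036, mean 0.11, test direction lower, camera adjusted p = 0.836). No gene was called among 14 endothelial genes (camera adjusted p = 0.990) or 11 erythroid genes (median -0.02, mean 0.08, test direction higher, camera adjusted p = 0.882). The counts of the last 4 lists were the same adjusted over the list alone. Leaving out a library raised the limma adjusted p of Foxc2 to 0.0738 (control replicate 1), 0.152 (food-restricted replicate 2) and 0.0754 (food-restricted replicate 3). For Podxl it became 0.184 and 0.0722 without control replicates 2 and 3, and 0.0565 and 0.133 without food-restricted replicates 1 and 3.

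A few stromal and macrophage genes rose in the food-restricted libraries. Of 17 stromal genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.000849, adjusted p = 0.0624 with an estimated correlation). The collagen Col3a1 rose from 295 ± 20.1 to 463 ± 58.2 normalized counts (0.64, limma adjusted p = 3.22e-06), Col1a1 by 0.28 (0.00347), Col1a2 by 0.38 (0.00595) and the receptor Pdgfra by 0.88 (0.00573). Aldh1a2, a retinoic acid enzyme, fell from 6517 ± 86.9 to 5976 ± 88.8 (-0.12, limma adjusted p = 0.0339), a call that ended with upper-quartile scaling (0.0592), trimmed-mean scaling (0.0549), the length trend removed (0.303) and both trends removed (0.188). Of 14 macrophage and leukocyte genes 3 rose, also when adjusted over the list alone (median 0.76, camera adjusted p = 0.000743, adjusted p = 0.0624 with an estimated correlation). These were Mrc1 (41.4 ± 10.8 to 85.7 ± 18.9, limma adjusted p = 0.0017), Csf1r (27.8 ± 7.12 to 60.4 ± 6.52, 0.00407) and Adgre1 (4.86 ± 3.81 to 19.5 ± 7.57, 0.0167, or 0.0626 with limma-voom). Single left-out libraries raised the limma adjusted p over the threshold for several of them. Without control replicate 1 it was 0.144 for Aldh1a2, 0.0694 for Pdgfra and 0.0526 for Csf1r. Without control replicate 2 it was 0.139 for Aldh1a2 and 0.0593 for Adgre1. Without control replicate 3 it was 0.0647 for Aldh1a2, 0.219 for Col1a2 and 0.101 for Adgre1. Without food-restricted replicate 1 it was 0.123 for Adgre1. Without food-restricted replicate 2 it was 0.0718 for Col1a1, 0.167 for Aldh1a2, 0.0582 for Csf1r and 0.0576 for Adgre1. Without food-restricted replicate 3 it was 0.0596 for Col1a1, 0.0543 for Col1a2, 0.0836 for Pdgfra, 0.162 for Aldh1a2 and 0.0685 for Adgre1.

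Sex-linked transcripts differed between the diets. Xist, expressed from the inactive X chromosome of females, rose from 17654 ± 840.3 to 26601 ± 547 normalized counts (0.59, limma adjusted p = 5.92e-25). The Y-linked genes Ddx3y (749 ± 58.3 to 336 ± 22.0), Uty (622 ± 73.6 to 331 ± 41.7), Kdm5d (618 ± 67.0 to 347 ± 12.3) and Eif2s3y (266 ± 18 to 149 ± 30.2) fell, with log2 fold changes of -1.15, -0.91, -0.83 and -0.85. All 5 were called, over all genes and adjusted over the list alone (median -0.85, camera adjusted p = 2.89e-07, adjusted p = 0.0870 with an estimated correlation).

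The core self-renewal genes did not pass the test, while 3 commitment genes rose. Six2 (ENSMUSG00000024134, GRCm38 chromosome 17, 85684277 to 85688274) was at 4160.2 ± 191 and 3989 ± 142 normalized counts (-0.06, limma adjusted p = 0.558), Cited1, a marker of the most naive progenitors, at 282 ± 32.9 and 269 ± 24.6 (-0.07, 0.848), Eya1 at 9353 ± 155 and 8990.4 ± 253 (-0.06, 0.446) and Osr1 at 755 ± 32.6 and 805 ± 12.1 (0.09, 0.587). Among 25 self-renewal genes Pax2 rose (0.28, limma adjusted p = 7.48e-06) and Meox1 (-0.42, 0.00152), Itga8 (-0.19, 0.00194) and Fgf20 (-0.41, 0.0311) fell. Adjusted over the list alone 1 rose and 4 fell, and the list did not pass camera (median -0.09, camera adjusted p = 0.0795). Fry called the list lower (fry adjusted p = 0.0249), and so did camera with the length and GC trends removed. Fgf20 had a limma adjusted p of 0.116, 0.236, 0.241 and 0.0975 without control replicates 1 and 3 and food-restricted replicates 2 and 3. Of 21 commitment genes, Lef1 (203 ± 25.5 to 313 ± 29.5; 0.63, limma adjusted p = 0.000112), the cadherin Cdh4 (2088 ± 35.9 to 2507 ± 136; 0.26, 0.000268) and Lhx1 (156 ± 22.1 to 232 ± 5.93; 0.58, 0.00185) rose. Wnt4, the inducer of the epithelial transition, was at 1223 ± 10.7 and 1381 ± 19.5 (0.18, limma adjusted p = 0.0735, or 0.0175 adjusted over the list alone). Wnt4 passed with upper-quartile scaling (0.0453), the stricter CPM filter (0.0472) and limma-voom (0.0483). Adjusted over the list alone 4 commitment genes rose and 1 fell; the list had a median of 0.15 (camera adjusted p = 2.40e-05, adjusted p = 0.0624 with an estimated correlation). Lef1 was also the 1 gene of 17 Wnt targets that rose, with 3 adjusted over the list alone (median 0.17, camera adjusted p = 0.00296, adjusted p = 0.161 with an estimated correlation).

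Cell division genes fell as a group. All 14 called genes of the 25 on the G2/M list fell, and 19 did adjusted over the list alone, with a median log2 fold change of -0.32 (camera adjusted p = 6.77e-26; adjusted p = 0.00606 with an estimated correlation). The proliferation marker Mki67 fell from 11783 ± 136 to 9455 ± 77.8 normalized counts (-0.32, limma adjusted p = 3.97e-11), the topoisomerase Top2a from 5760.1 ± 151 to 4444 ± 255 (-0.38, 4.31e-10) and the kinetochore gene Cenpf from 4337 ± 58.9 to 3328 ± 84.9 (-0.38, 7.92e-10). Of 62 histone genes that are transcribed in S phase, 34 fell, 47 adjusted over the list alone, and none rose (median -0.46, or -0.28 with the length trend removed; camera adjusted p = 3.41e-39; adjusted p = 0.00676 with an estimated correlation). Hist1h1d fell from 2116 ± 151 to 1469.8 ± 41.2 (-0.52, limma adjusted p = 1.55e-10) and Hist1h4b from 564 ± 85.7 to 333 ± 29.5 (-0.75, 3.96e-08). Of 27 S phase genes 5 fell, 7 adjusted over the list alone (median -0.13, camera adjusted p = 1.12e-07, adjusted p = 0.0624 with an estimated correlation). They were Mcm3 (-0.25, limma adjusted p = 0.00126), Rrm1 (-0.24, 0.00173), Pola1 (-0.23, 0.00881), Mcm6 (-0.18, 0.0168) and Mcm5 (-0.24, 0.0171). Left-out libraries gave a limma adjusted p of 0.0608 for Rrm1 without control replicate 2 and 0.0678, 0.0895 and 0.0555 for Pola1 without control replicates 2 and 3 and food-restricted replicate 2. Without control replicates 1 and 2 and food-restricted replicates 1 and 2 it was 0.128, 0.130, 0.117 and 0.0762 for Mcm6 and 0.0962, 0.0893, 0.113 and 0.0669 for Mcm5.

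**Figure D2:**
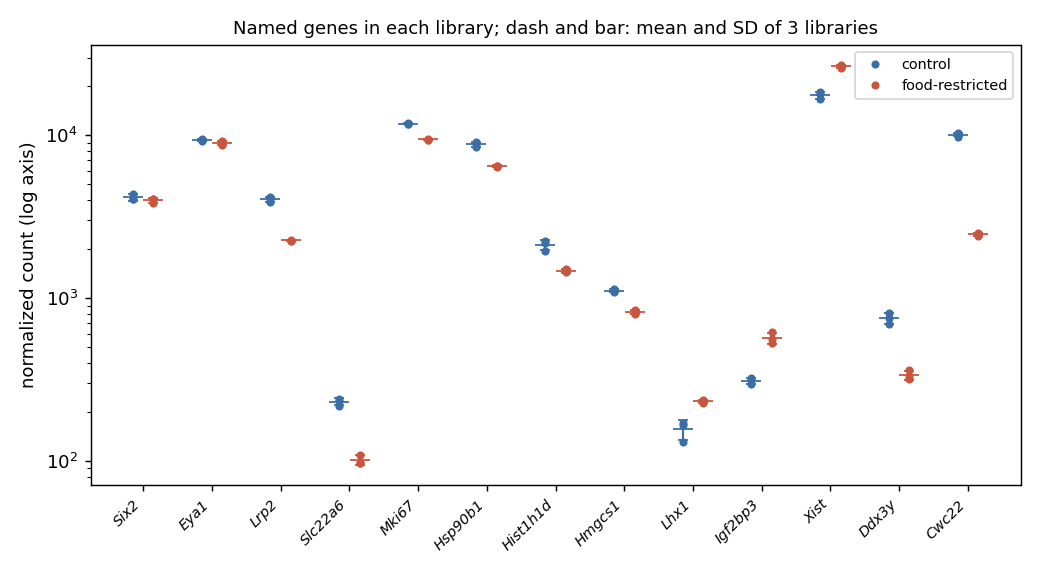
Normalized counts (log axis) of named genes in each library, with the mean and SD of the 3 libraries of a diet. Six2 and Eya1 overlap between the diets, Lrp2 goes from 4045 to 2259, and Cwc22 from 10073 to 2466.

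The lists of endoplasmic reticulum chaperones and of sterol synthesis enzymes were both lower. Of 19 unfolded protein response genes 9 fell, 13 adjusted over the list alone (median -0.31, camera adjusted p = 1.70e-17; adjusted p = 0.0303 with an estimated correlation). Hsp90b1 fell from 8787 ± 342 to 6446 ± 78.9 normalized counts (-0.45, limma adjusted p = 9.21e-15), Calr from 6672 ± 241 to 5194 ± 70.8 (-0.36, 1.55e-10), Hspa5 from 6702 ± 106 to 5368 ± 118 (-0.32, 4.45e-09) and Pdia3 from 4229.9 ± 90.4 to 3331 ± 87.1 (-0.34, 2.54e-08). Of 23 sterol genes 5 fell, 14 adjusted over the list alone (median -0.27, camera adjusted p = 1.19e-09; adjusted p = 0.0242 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 1112 ± 26.7 to 821 ± 21.3 (-0.44, limma adjusted p = 2.54e-06) and Insig1 from 355 ± 5.28 to 254 ± 26.3 (-0.49, 0.00128). Sqle, the squalene epoxidase, fell as well (-0.32, 0.0261). The limma adjusted p of Sqle was 0.273 without control replicate 3, and 0.112 and 0.153 without food-restricted replicates 1 and 3.

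Lists of translation and of mitochondrial energy metabolism were lower by small amounts at the preset correlation. Of 84 ribosomal protein genes 20 fell, 44 adjusted over the list alone, among them Rps3 (9529 ± 76.9 to 7801 ± 780.4, -0.29, limma adjusted p = 2.42e-07) and Rpl7 (-0.22, 2.21e-05); the median was -0.13 (camera adjusted p = 3.90e-24, adjusted p = 0.126 with an estimated correlation). Of 49 nuclear-encoded oxidative phosphorylation genes 9 fell, 21 adjusted over the list alone, with Cox6c at -0.43 (limma adjusted p = 4.95e-05) and Ndufa5 at -0.56 (0.000129). That list had a median of -0.16 (camera adjusted p = 3.08e-12, adjusted p = 0.0624 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 7 fell, 8 adjusted over the list alone (median -0.24, camera adjusted p = 7.31e-13, adjusted p = 0.0816 with an estimated correlation). Their median relative to the control mean was -0.0966 in food-restricted replicate 1, beside -0.0817 in control replicate 1, and -0.281 and -0.299 in food-restricted replicates 2 and 3. That of the ribosomal proteins was -0.0470, -0.134 and -0.217 in food-restricted replicates 1 to 3. The tricarboxylic acid cycle list had 5 falling genes of 21, 7 adjusted over the list alone (median -0.09, camera adjusted p = 1.27e-05, adjusted p = 0.0868 with an estimated correlation): Idh1 (-0.35, limma adjusted p = 0.000831), Sucla2 (-0.32, 0.00275), Mdh1 (-0.27, 0.0055), Pcx (-0.31, 0.0116) and Fh1 (-0.33, 0.0134). The limma adjusted p was 0.115 for Pcx without control replicate 1, 0.116 for Fh1 without control replicate 3, and 0.105 for Pcx and 0.108 for Fh1 without food-restricted replicate 3. Short transcripts were lower and long ones higher in the food-restricted libraries: over 10760 protein-coding genes with a mean of at least 50, the Spearman correlation of fold change with exon length was 0.237 and with GC content 0.232, across genes, which are not independent replicates. With each library's length and GC trends removed the ribosomal proteins had a median of -0.057 (camera adjusted p = 3.58e-09) and the tricarboxylic acid cycle genes one of -0.056 (3.33e-05). The mitochondrially encoded mRNAs then had a median of -0.045 and no longer passed (0.0616).

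**Figure D3:**
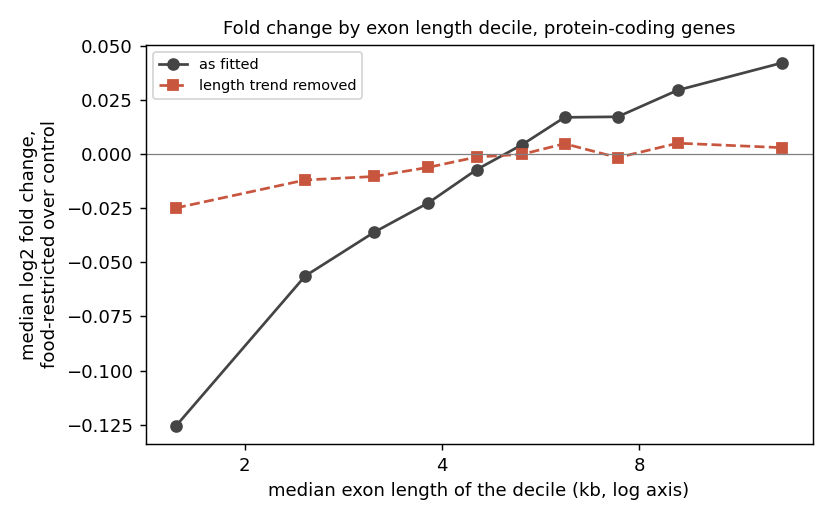
Median log2 fold change, food-restricted over control, of protein-coding genes in 10 groups of rising exon length (horizontal axis, kb, log axis), as fitted and with each library's length trend removed. As fitted, the medians run from -0.13 in the shortest group to 0.04 in the longest; with the trend removed they lie between -0.025 and 0.0052.

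Several smaller metabolic lists were lower with few called genes. In fatty acid synthesis (14 genes) Scd2 (-0.20, limma adjusted p = 3.6e-05), Elovl5 (-0.36, 0.00468) and Fads2 (-0.32, 0.0285) fell, the same 3 adjusted over the list alone (median -0.07, camera adjusted p = 0.00885, adjusted p = 0.0938 with an estimated correlation). In ribosome biogenesis (29 genes) Npm1 (-0.22, limma adjusted p = 5.67e-06), Ncl (-0.12, 0.00525) and Wdr43 (-0.18, 0.0287) fell, 6 adjusted over the list alone (median -0.04, camera adjusted p = 0.00300, adjusted p = 0.0841 with an estimated correlation). In the pentose phosphate and nucleotide list (24 genes) only Taldo1 fell (-0.31, limma adjusted p = 0.0173), also adjusted over the list alone (median -0.08, camera adjusted p = 0.0401, adjusted p = 0.129 with an estimated correlation). In the hypoxia list (25 genes) P4ha1 (-0.31, limma adjusted p = 0.000431) and Ndrg1 (-0.40, 0.0194) fell, 3 adjusted over the list alone (median -0.07, or -0.013 with length and GC trends removed; camera adjusted p = 0.0469, adjusted p = 0.131 with an estimated correlation). The camera adjusted p of the pentose list became 0.137 without control replicate 1 and 0.0589 and 0.0734 without food-restricted replicates 2 and 3, and that of the hypoxia list 0.199 without control replicate 1 and 0.0693 and 0.0720 without food-restricted replicates 1 and 2. Without control replicate 1 the limma adjusted p was 0.0538 for Ncl, 0.0624 for Wdr43, 0.225 for Taldo1 and 0.181 for Ndrg1. Without control replicate 2 it was 0.106 for Fads2, 0.108 for Ncl, 0.0653 for Wdr43 and 0.200 for Ndrg1. Without control replicate 3 it was 0.173 for Fads2, 0.212 for Wdr43 and 0.0784 for Taldo1. Without food-restricted replicate 1 it was 0.0619 for Fads2. Without food-restricted replicate 2 it was 0.0597 for Ncl, 0.232 for Wdr43, 0.0846 for Taldo1 and 0.145 for Ndrg1. Without food-restricted replicate 3 it was 0.223 for Fads2, 0.0940 for Ncl, 0.129 for Wdr43, 0.111 for Taldo1 and 0.0790 for Ndrg1.

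A minority of the insulin-like growth factor signalling genes and of the imprinted genes rose, and their list medians were near 0. Igf2bp3, an RNA-binding protein of fetal tissues, rose from 312 ± 13.0 to 569 ± 44.9 normalized counts (0.86, limma adjusted p = 9.89e-11), and the imprinted growth factor Igf2 from 14291 ± 420.0 to 16225 ± 215 (0.18, 1.85e-05). Txnip rose from 603 ± 39.5 to 857 ± 44.0 (0.51, 1.56e-06) and Igf2bp1 from 2518 ± 135 to 2970.0 ± 116 (0.24, 0.000606). On the list of 28 insulin, IGF and FoxO genes 7 rose and Bcl6 fell (-0.92, limma adjusted p = 0.0371); adjusted over the list alone 7 rose and 4 fell (median 0.10, camera adjusted p = 0.00114, adjusted p = 0.126 with an estimated correlation). Of 30 imprinted genes 5 rose: Igf2, Meg3 (0.57, limma adjusted p = 0.000408), Zim1 (0.38, 0.000625), Peg10 (1.09, 0.0018) and Nnat (0.38, 0.00285). Adjusted over the list alone 7 rose and 1 fell (median 0.06, camera adjusted p = 0.000822, adjusted p = 0.0624 with an estimated correlation). Bcl6 had a limma adjusted p of 0.151, 0.305, 0.110 and 0.147 without control replicates 1 and 3 and food-restricted replicates 1 and 2.

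Nutrient sensing and the amino acid response changed in single genes, and their lists did not pass camera. Fry called the mTORC1 list higher (fry adjusted p = 0.0320) and the methionine and folate list lower (0.0489). Mtor was at 1673 ± 60.04 and 1834 ± 136 normalized counts (0.13, limma adjusted p = 0.213, or 0.0301 without food-restricted replicate 1) and its inhibitor Tsc1 at 1282 ± 33.8 and 1325 ± 36.9 (0.05, 0.784). Of 40 mTORC1 components Rptor (0.22, limma adjusted p = 0.00865) and Rps6kb2 (0.33, 0.0431) rose and Sesn3 fell (-0.17, 0.0153), with 5 higher and 1 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.0584, and 0.0209 and 0.0496 without control replicate 2 and food-restricted replicate 3). On the list of 33 amino acid response genes Ppp1r15a (0.54, limma adjusted p = 2.07e-06) and the transporter Slc7a5 (0.61, 0.000142) rose and Psat1 (-0.44, 0.00606), Phgdh (-0.26, 0.00635) and Mthfd2 (-0.39, 0.0352), enzymes of serine and folate metabolism, fell, the same numbers adjusted over the list alone (median -0.04, mean 0.0030, test direction lower, camera adjusted p = 0.878). Mat2a, which makes the methyl donor S-adenosylmethionine, was at 2574 ± 59.9 and 2596 ± 60.3 (0.01, limma adjusted p = 0.946). On the methionine and folate list of 31 genes 2 rose, Slc7a5 among them, and Mthfd2 fell, the same numbers adjusted over the list alone (median -0.09, camera adjusted p = 0.330). Without control replicate 1 the limma adjusted p was 0.147 for Rps6kb2, 0.0621 for Sesn3, 0.0731 for Psat1 and 0.141 for Mthfd2. Without control replicate 2 it was 0.0831 for Rps6kb2 and 0.0605 for Sesn3. Without control replicate 3 it was 0.0630 for Rptor, 0.0986 for Rps6kb2, 0.0672 for Sesn3 and 0.181 for Mthfd2. Without food-restricted replicate 2 it was 0.0916 for Rptor, 0.235 for Rps6kb2, 0.116 for Sesn3 and 0.183 for Mthfd2. Without food-restricted replicate 3 it was 0.124 for Rps6kb2, 0.0839 for Sesn3, 0.104 for Psat1 and 0.134 for Mthfd2.

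Chromatin enzymes and non-coding RNAs moved in both directions. Of 30 DNA and histone methylation enzymes the demethylase Kdm6b (0.20, limma adjusted p = 0.000908), Kmt2d (0.13, 0.0247) and Tet3 (0.14, 0.039) rose and the deacetylase Hdac2 fell (-0.22, 0.00242), 7 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.0446, adjusted p = 0.288 with an estimated correlation). Of 14 long non-coding RNAs Neat1 (0.75, limma adjusted p = 1.12e-11), Xist, Meg3 and Gm26917 (0.24, 1.12e-11) rose and Malat1 fell (-0.09, 0.00189), 6 and 4 adjusted over the list alone (median 0.08, camera adjusted p = 0.000157, adjusted p = 0.0624 with an estimated correlation). Of 5 structural RNAs Rn7sk, the regulator of transcription elongation (-0.32, limma adjusted p = 1.65e-14), Rny3 (-0.56, 0.00364) and Gm42418 (-0.40, 4.86e-06) were called lower, 4 adjusted over the list alone (median -0.40, camera adjusted p = 8.41e-10; adjusted p = 0.0446 with an estimated correlation). Food-restricted replicate 1 did not share this: its list median relative to the control mean was 0.029, among the controls (-0.154, 0.137 and 0.017), against -0.495 and -0.741 in food-restricted replicates 2 and 3. The call of Gm42418 ended under limma-voom (log2 fold change 0.013, limma adjusted p = 0.968) and that of Rn7sk with the length trend removed (0.795), though not with both trends removed (0.00104). Rny3 lost its call with the length trend removed (0.447), with both removed (0.451), with a pseudocount of 0.1 (0.12) and with a filter on CPM (0.0804). With both trends removed the structural RNA list had a median of -0.16. With both trends removed the methylation list had a camera adjusted p of 0.77, and Kdm6b (0.0536), Kmt2d (0.849) and Tet3 (0.344) lost their calls. The camera adjusted p of the methylation enzymes was 0.0843 and 0.141 without control replicates 1 and 3, and 0.12 and 0.0746 without food-restricted replicates 2 and 3. Without control replicate 1 the limma adjusted p was 0.211 for Tet3. Without control replicate 2 it was 0.210 for Kmt2d, 0.0540 for Tet3, 0.0558 for Malat1 and 0.106 for Rny3. Without control replicate 3 it was 0.180 for Kmt2d, 0.157 for Tet3, 0.0618 for Malat1 and 0.218 for Rny3. Without food-restricted replicate 2 it was 0.332 for Kmt2d, 0.348 for Tet3 and 0.0545 for Malat1. Without food-restricted replicate 3 it was 0.0559 for Hdac2, 0.250 for Kmt2d, 0.194 for Tet3, 0.121 for Malat1 and 0.526 for Rny3.

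The oxidative stress and immediate-early lists each held called genes of both directions, and neither passed camera. Hmox1, the haem-degrading enzyme, rose from 19.6 ± 10.4 to 67.1 ± 10.8 normalized counts (1.87, limma adjusted p = 1.79e-05), while Sod1 (-0.43, 7.25e-06), Prdx1 (-0.27, 0.00321), Taldo1 and Fth1 (-0.18, 0.0433) fell. The 25 oxidative stress genes had 1 rising and 6 falling adjusted over the list alone (median -0.05, mean 0.03, test direction lower, camera adjusted p = 0.0503, and 0.0479 without food-restricted replicate 3). Fry called this list lower (fry adjusted p = 0.000219). Of 24 immediate-early and dissociation genes Jun (0.31, limma adjusted p = 0.000359), Hspa1b (1.15, 0.00414), Dnajb1 (0.28, 0.0245) and Hspa1a (0.92, 0.028) rose and Hspa8 (-0.38, 5.34e-12), Fos (-0.48, 6.97e-07), Fosb (-0.34, 0.000566) and Socs3 (-0.41, 0.0155) fell (median -0.01, mean 0.06, test direction lower, camera adjusted p = 0.574), with 6 rising and 4 falling adjusted over the list alone. Without control replicate 1 the limma adjusted p was 0.225 for Taldo1, 0.218 for Fth1, 0.0720 for Hspa1a and 0.154 for Socs3. Without control replicate 2 it was 0.0508 for Fth1, 0.0847 for Hspa1a and 0.0848 for Dnajb1. Without control replicate 3 it was 0.141 for Fth1, 0.0518 for Hspa1a, 0.102 for Dnajb1, 0.0784 for Taldo1 and 0.0503 for Socs3. Without food-restricted replicate 1 it was 0.103 for Fth1, 0.0738 for Dnajb1 and 0.202 for Socs3. Without food-restricted replicate 2 it was 0.0501 for Prdx1, 0.0846 for Taldo1, 0.0719 for Fth1, 0.172 for Hspa1a and 0.0972 for Dnajb1. Without food-restricted replicate 3 it was 0.111 for Taldo1, 0.148 for Fth1, 0.0987 for Hspa1b, 0.124 for Hspa1a and 0.0579 for Dnajb1.

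The lists of extracellular matrix genes and of FGF and MAPK, BMP and TGF-beta, and Hippo targets did not pass camera. Of 26 extracellular matrix genes 3 rose, Frem1 (0.30, limma adjusted p = 4.49e-06), fibronectin Fn1 (0.37, 5.33e-06) and Hspg2 (0.28, 1.07e-05), and 3 fell, Sparc (-0.31, 5.28e-08), N-cadherin Cdh2 (-0.23, 0.000476) and Itga8, 4 and 4 adjusted over the list alone (camera adjusted p = 0.295). Of 19 FGF and MAPK targets the receptor Fgfr1 (0.22, limma adjusted p = 2.31e-05) and Spred3 (0.38, 0.00958) rose, 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.753). Of 19 BMP and TGF-beta targets Tgfbi rose (0.19, limma adjusted p = 0.00145) and Id1 fell (-0.55, 0.0047), 1 and 2 adjusted over the list alone (camera adjusted p = 0.448). No Hippo target of 21 was called, 1 rising and 1 falling adjusted over the list alone (median 0.03, mean -0.11, test direction higher, camera adjusted p = 0.590). The limma adjusted p was 0.0755 for Spred3 and 0.0643 for Id1 without control replicate 1, 0.110 for Spred3 without food-restricted replicate 2, and 0.0761 for Tgfbi and 0.138 for Id1 without food-restricted replicate 3.

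Lists of fuel use, autophagy, cell death and glucocorticoid response did not pass camera either. Fry called the fatty acid oxidation list lower (fry adjusted p = 0.0398) and the autophagy list higher (0.00338). Of 21 fatty acid oxidation genes Cpt1a, the gatekeeper of mitochondrial fatty acid import, rose (0.30, limma adjusted p = 0.00407) and Acadl fell (-0.34, 0.0095), also adjusted over the list alone (camera adjusted p = 0.590). Of 19 glycolysis genes Hk2 fell (-0.21, limma adjusted p = 0.0317), 2 adjusted over the list alone (camera adjusted p = 0.307). Of 36 autophagy and lysosome genes Ulk1 (0.24, limma adjusted p = 0.0204) and Wipi1 (0.33, 0.0264) rose, also adjusted over the list alone (camera adjusted p = 0.0584, and 0.0496 without food-restricted replicate 3). Of 23 p53 targets Bcl2l11 rose (0.21, limma adjusted p = 0.0157) and Trp53inp1 fell (-0.28, 0.00598), 2 and 1 adjusted over the list alone (camera adjusted p = 0.878). Of 18 glucocorticoid response genes Sgk1 rose (0.50, limma adjusted p = 0.0342) and Fam107a fell (-0.26, 0.00258), also adjusted over the list alone (camera adjusted p = 0.764). Without control replicate 1 the limma adjusted p was 0.0684 for Hk2, 0.105 for Ulk1, 0.320 for Wipi1 and 0.0656 for Sgk1. Without control replicate 2 it was 0.0599 for Acadl, 0.149 for Hk2, 0.0957 for Bcl2l11, 0.145 for Sgk1 and 0.0501 for Fam107a. Without control replicate 3 it was 0.0885 for Hk2, 0.0855 for Ulk1, 0.0509 for Bcl2l11, 0.0638 for Trp53inp1 and 0.0998 for Sgk1. Without food-restricted replicate 1 it was 0.0724 for Hk2, 0.0583 for Wipi1 and 0.236 for Sgk1. Without food-restricted replicate 2 it was 0.0802 for Hk2, 0.134 for Ulk1, 0.0605 for Wipi1 and 0.0741 for Bcl2l11. Without food-restricted replicate 3 it was 0.0955 for Hk2, 0.128 for Ulk1, 0.156 for Wipi1, 0.0802 for Bcl2l11, 0.157 for Sgk1 and 0.0615 for Fam107a.

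Among the single genes with the largest falls, several serve transport and metabolism in the proximal tubule. The peptide transporter Slc15a2 (ENSMUSG00000022899, GRCm38 chromosome 16, 36750178 to 36784962) fell from 169 ± 32.0 to 28.4 ± 8.70 normalized counts (log2 fold change -2.56, limma adjusted p = 2.52e-14). Pck1, the rate-limiting enzyme of gluconeogenesis, fell from 169 ± 10.2 to 66.8 ± 11.6 (-1.33, 2.55e-08) and the secreted peroxidase Gpx3 from 634 ± 10.9 to 288 ± 22.5 (-1.14, 3.19e-15). Spp1 (-1.58, 1.16e-06), Tmem27 (-1.39, 1.85e-06), Plau (-1.25, 7.88e-06) and Cldn2 (-1.16, 3.16e-05) fell too, beside Ass1, Slc22a6 and Ddx3y. The smallest p belonged to the splicing factor Cwc22 (ENSMUSG00000027014, GRCm38 chromosome 2, 77881159 to 77946375), which fell from 10073 ± 246 to 2466 ± 52.6 (-2.03, limma adjusted p = 1.91e-48); it lies in a segment whose copy number is known to vary among mouse stocks.

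The largest rise by the same rule was that of Tpm3-rs7, a tropomyosin-related sequence (GRCm38 chromosome 14, 113314608 to 113316713), from 27.9 ± 10.4 to 148 ± 29.2 normalized counts (2.42, limma adjusted p = 3.32e-12). The zinc finger gene Zfp979 rose from 34.4 ± 4.09 to 117 ± 10.3 (1.74, 8.48e-09), Itpr3 from 36.9 ± 14.6 to 76.1 ± 0.547 (1.10, 0.00198), Arsg from 61.3 ± 22.1 to 113 ± 6.36 (0.93, 0.00111) and the transcription factor Nfatc1 from 80.5 ± 15.8 to 147 ± 23.8 (0.87, 0.000332). Begain (0.95, 0.0169), Sgsm1 (0.84, 0.00868) and Cyp4f13 (0.84, 0.00925) rose, beside Peg10, Mrc1, Pdgfra and Igf2bp3. Left-out libraries gave a limma adjusted p of 0.184 for Begain, 0.170 for Cyp4f13 and 0.0694 for Pdgfra without control replicate 1, and 0.0664 for Begain, 0.144 for Sgsm1 and 0.0525 for Itpr3 without control replicate 3. It was 0.127 and 0.0544 for Begain without food-restricted replicates 1 and 2, and 0.167 for Sgsm1, 0.0694 for Cyp4f13 and 0.0836 for Pdgfra without food-restricted replicate 3. Outside the rule, the pseudogene Gm6166 stood at 3.16 ± 2.22 and 99.5 ± 5.33 (4.75, limma adjusted p = 2.31e-14) and the androgen-regulated kidney gene Kap at 102 ± 16.3 and 18.1 ± 8.24 (log2 fold change -2.53).

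The authors' deposited table held 799 genes with an adjusted p under 0.05, 360 higher and 439 lower under food restriction, and 793 of these were also called by limma in the same direction. The log2 fold changes in the authors' deposited table were -2.03 for Cwc22, -2.49 for Slc15a2, -0.84 for Lrp2, -0.32 for Mki67, 0.88 for Igf2bp3 and 1.77 for Zfp979. Other genes called by limma did not pass in the authors' deposited table. Its adjusted p was 0.835 for Rny3, 0.666 for Gm42418, 0.255 for mt-Cytb, 0.206 for mt-Co1, 0.152 for Bcl6, 0.146 for Sgk1, 0.118 for Socs3, 0.114 for Begain, 0.110 for Wipi1 and 0.110 for Sqle. In the authors' deposited table it was 0.101 for Adgre1, 0.101 for Rps6kb2, 0.0978 for Fads2, 0.0955 for Fgf20, 0.0910 for Kmt2d, 0.0893 for Mthfd2, 0.0892 for Podxl and 0.0803 for Hspa1a. The authors' deposited table also gave 0.0756 for Cyp4f13 and Hspg2, 0.0740 for Sgsm1 and Malat1, 0.0647 for Ndrg1, 0.0586 for Fth1, 0.0577 for Dnajb1, 0.0550 for Col1a2 and 0.0532 for Mcm5.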

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

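The tests with the length and GC trends removed and with trimmed-mean scaling were chosen after the results were seen; the other settings were chosen before the data were examined. The planned edgeR and DESeq2 tests were not run, and the authors' size factors, planned as an alternative, served as the scaling throughout. A filter on a mean of at least 1 removed 0 genes, since the lowest mean tested was 1.09, and so gave no value. The count of 1193 called genes was 961 to 1668 under the other scalings, filters, pseudocounts, limma-voom, trend removals and the threshold of 0.1, and 125 with an absolute log2 fold change of at least 1, a rule that takes fewer genes by construction. Leaving out 1 library at a time gave 564 to 1357 genes; each such fit had fewer samples. Upper-quartile scaling moved the share of falling calls from 52.8% to 46.5%.

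Of the 24 lists that passed, 6 passed camera with the correlation estimated. Leaving out single libraries gave 21 to 25. Fry called 25 lists, not all of them the lists that camera called. It called the oxidative stress list lower (fry adjusted p = 0.000219) and the autophagy list higher (0.00338). The mTORC1 list was also called higher (fry adjusted p = 0.0320), and the methionine and folate list (0.0489) and the fatty acid oxidation list (0.0398) lower. Fry did not call the ribosomal proteins (fry adjusted p = 0.0668) or the mitochondrially encoded mRNAs (0.110). No list called in either fit turned its direction; 707 values lay on the same side of the threshold, 23 were no longer past it and 16 were newly past it. The methylation enzymes lost their call in the largest number of settings and lay at a camera adjusted p of 0.764 with the length trend removed. The hypoxia and pentose lists lost theirs with upper-quartile scaling (0.0639 for both) and trimmed-mean scaling (0.0578 and 0.0538). The mTORC1 list passed with upper-quartile and trimmed-mean scaling (0.0355 and 0.0451), as did autophagy (0.0392 and 0.0471). With every gene of at least 1 count those lists and the oxidative stress list passed (0.0333 for all), and the oxidative stress list also with the stricter CPM filter (0.0453) and with pseudocounts of 0.1 (0.0435) and 10 (0.0483). The stricter filter ended the calls of the pentose list (0.0593) and the methylation enzymes (0.0904), a pseudocount of 10 that of the methylation enzymes (0.0515), and removing both trends that of the hypoxia list (0.0568). With both trends removed, self-renewal genes passed as lower (median -0.08, 0.0125), as did glycolysis genes (0.0159); the cause was not tested.

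Among the named genes, 3211 values stayed on the same side of the threshold with no call turned, 253 were no longer past it and 38 were newly past it. Beside those given in the report, removing the length trend ended the calls of Fgf20 (0.122), Acadl (0.0524), Fads2 (0.0516), Taldo1 (0.0725), Mthfd2 (0.058), Fth1 (0.097), Kmt2d (0.232) and Tet3 (0.211). Removing both trends ended those of Rptor (0.131), Rps6kb2 (0.0934), Ulk1 (0.138), Wdr43 (0.0591), Fgf20 (0.156), Acadl (0.082), Mthfd2 (0.0553) and Fth1 (0.066). Fth1 also lost its call with upper-quartile (0.0651) and trimmed-mean scaling (0.0617). Under limma-voom the calls of Bcl6 (0.0743), Sgk1 (0.0879), Socs3 (0.0542) and, by the narrowest margin, Sqle ended. A pseudocount of 0.1 ended those of Fgf20 (0.0538), Mthfd2 (0.0506), Kmt2d (0.0678), Tet3 (0.0637), Rps6kb2 (0.0546), Wipi1 (0.0564), Sgk1 (0.0568), Sqle (0.0536), Bcl6 (0.0572) and Fth1 (0.0596), and a pseudocount of 10 those of Tet3 (0.0528), Aldh1a2 (0.0521), Bcl6 (0.0534) and Malat1 (0.0669). Testing every gene with at least 1 count ended those of Tet3 (0.0621), Aldh1a2 (0.0805) and Fth1 (0.0566), and the stricter CPM filter those of Kmt2d (0.0627) and Tet3 (0.0504). The 1 reversal was Gm42418, with a log2 fold change of 0.013 under limma-voom; the cause was not tested.

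The replicate numbers did not pair the libraries. Correlations of same-numbered deviations were -0.11, 0.03 and -0.07 over 10060 genes. With the number as a block, 980 genes were called, 976 of them shared with the fit without it, and 22 lists passed; the hypoxia list (0.0539) and the methylation enzymes (0.0622) were past the threshold only without the block. So were Hk2 (0.0594), Rps6kb2 (0.0598), Wdr43 (0.0603), Malat1 (0.0693), Tet3 (0.0864), Fth1 (0.0877), Kmt2d (0.0879) and Aldh1a2 (0.101) among the genes named in the report. At these depths the test recovered 38.8% of the simulated genes with the smallest change, so changes of that size can be missed.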

Other observations

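All tests in this part were chosen only after the results were seen. Grouping the tested protein-coding genes by shared symbol stem gave 111 families of at least 10 genes, of which 3 passed camera and 0 with an estimated correlation. The 14 semaphorin genes (Sema), guidance cues for axons and vessels, had 4 members that rose and none that fell, with a median log2 fold change of 0.16 (camera adjusted p = 0.0273, adjusted p = 0.542 with an estimated correlation). Sema3d (0.53, limma adjusted p = 1.54e-05), Sema6a (0.42), Sema4g (0.22) and Sema4c (0.22) rose. Of 17 Arhgef genes 1 rose (median 0.11, camera adjusted p = 0.0127) and of 14 proteasome genes of the Psmd stem 1 fell (median -0.13, camera adjusted p = 0.0425), both with an adjusted p = 0.542 with an estimated correlation. With the length and GC trends removed the 3 families had adjusted p of 0.174, 0.194 and 0.0560.

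The proximal tubule genes were lower in the food-restricted libraries, with a weighted mean log2 fold change of -0.87 (SE 0.029). Fewer mature or other kidney cells of every kind in the sort would lower the other cell type lists as well, and the lowest of their 6 medians was -0.036, for the ureteric genes, 0.80 (SE 0.240) from the proximal tubule median. The exon length and GC trends are argued against as the whole cause, since the median with both removed was -0.83 (SE 0.104). The SE of a list median or of a difference of medians, here and in the next paragraph, comes from 2000 bootstrap draws of the list's genes. It measures the spread among genes and not that between libraries. The SE of the weighted mean takes the genes as independent. Less proximal tubule RNA in the sorted cells, which could come from fewer such cells passing the GFP gate, would shift the members alike, and a chi-square test of their heterogeneity gave p = 0.000344. Members that progenitors also express would be diluted, so such a loss and an effect of the diet within the progenitors, itself untested, cannot be told apart.

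Several lower lists coincide with the trend of fold change with exon length. The Spearman correlations with exon length in single libraries were -0.214, -0.152 and -0.128 for the controls and 0.110, 0.143 and 0.194 for the food-restricted libraries. With length and GC trends removed, the medians of the G2/M list (-0.30, SE 0.017), the histones (-0.32, SE 0.035, from -0.46), the unfolded protein response (-0.25, SE 0.059), ribosomal proteins (-0.057, SE 0.012, from -0.13) and oxidative phosphorylation (-0.11, SE 0.022) still passed at the preset correlation, which argues against the trends as their whole cause. No list was tested with an estimated correlation after the trends were removed, so for all of these lists the argument holds at the preset correlation only. The ribosomal proteins and oxidative phosphorylation did not pass with an estimated correlation even before the trends were removed (adjusted p = 0.126 and 0.0624 with an estimated correlation). The mitochondrially encoded mRNAs went from -0.24 (SE 0.062) to -0.045 (SE 0.031) and their call as a list ended because the fold shrank. RNA or library quality that varies with transcript length or GC is thus a candidate explanation for that list. With both trends removed mt-Cytb (limma adjusted p = 2.51e-05) and mt-Co1 (0.00455) kept their calls, while mt-Nd6 (0.204) and mt-Nd4 (0.495) lost theirs. What gave rise to the trends, and whether diet had a part in it, stays open.

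Y-linked genes were lower (weighted mean -0.95, SE 0.048, chi-square heterogeneity p = 0.0383) and Xist higher in the food-restricted libraries. A larger share of female embryos in those pools may account for this: the 4 X-linked genes that escape inactivation, Kdm6a (0.09), Eif2s3x (0.09), Kdm5c (0.14) and Ddx3x (0.06), had a weighted mean of 0.088 (SE 0.023), the direction this needs, though none was called singly. The SE of each weighted mean takes the genes as independent, though all were measured in the same 6 libraries, and may be too small. The X-linked values were not corrected for the exon length trend, so the mean of 0.088 does not settle the question. Whether the 3 libraries of a diet share 1 pool of embryos could not be decided. The mean within-diet SD of the 5 sex-linked genes was 0.133, at the 94.2 percentile of sets of like level (median 0.0973). Such sets do not give the spread in sex share expected between independent pools, so the percentile cannot decide it. Ddx3y was at 750, 691 and 807 in control replicates 1 to 3 and at 361, 326 and 320 in food-restricted replicates 1 to 3. Libraries from 1 shared pool would not be independent replicates of the diet. An effect of diet on the survival of male embryos stays open, untested.

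Regrouping the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05: the real split, the 1 split with as many, called 1193 genes, the highest other 30, and 24 lists passed, the highest other 13. Each other split sets 2 libraries of a diet beside 1 of the other and so keeps part of the diet difference. Camera called 3 to 13 lists in those 9 splits: the proximal tubule, G2/M and histone lists in all 9, and the sterol, ribosomal protein and unfolded protein response lists in 6 each. A camera adjusted p such as 7.73e-37 therefore sets a list against the other genes and does not measure how rarely another grouping of the libraries would call it.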
